A study of Mus musculus with 2 samples.

How the data were processed

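Genomic DNA from kidneys of male C57BL/6 mice, a common inbred laboratory strain, aged 6 weeks was profiled by hydroxymethylated DNA immunoprecipitation sequencing (hMeDIP-seq). In this assay an antibody against 5-hydroxymethylcytosine (5hmC), the oxidation product that TET enzymes make from 5-methylcytosine, pulls down DNA fragments that carry the mark, and the recovered fragments are sequenced. The groups are 1 hMeDIP library made with the 5hmC antibody and 1 input library without antibody. The labels do not say how many animals the DNA came from. With 1 library per group there is no replicate error and no test between conditions, and a test on the fragments compares these libraries only. All intervals below are 95% intervals that cover counting error only, except that of the matched X difference, which comes from resampled blocks of sequence, and sequenced reads without molecular identifiers are not independent molecules.

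The authors deposited 1 file of mapped positions per library and 1 peak list for the hMeDIP library. The submitters' processing notes name CASAVA, Bowtie 1.0.0 and the mouse genome build mm9. The alignment settings and read filters are not given in the sources used here. Each deposited line of a position file gives a stretch of 350 bp, a strand and a count. From the values alone, a line was read here as 1 fragment extended to that length and its count as the reads that share it, steps the labels do not describe. No chromosome, start, end and strand stood on more than 1 line. The lines gave 11424027 fragments from 11634110 reads for hMeDIP and 8316507 fragments from 8368122 reads for input. Lines of another length numbered 18 and 163. Per the file headers, the peaks were called with MACS. The caller's version, its control and its threshold are not given in the sources used here. The score that the authors' peak list gives each peak started at 50, and is used here only to rank and filter peaks within that list. The track line of the list carries a numbered range after the word hMeDIP, whose meaning is not given, so it is open whether the peaks were called on this library alone.

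Each fragment was assigned to a peak, bin or chromosome by its midpoint. A ratio is the share of hMeDIP fragments in a region divided by the share of input fragments there, each relative to all fragments of its library, with an exact conditional binomial (Clopper-Pearson) interval. A ratio of 1 is therefore the genome-wide mean of these libraries, not a fixed amount of 5hmC. Shares of 1 library carry an exact Clopper-Pearson interval. The median over peaks was taken after adding a pseudocount of 1 fragment in each library. Broad domains were measured in 100 kb bins of the autosomes with at least 50 input fragments. A bin was called high or low when its log2 ratio passed 0.5 in size and its interval excluded 0. Chromosome lengths were taken as the highest coordinate in the files. The named regions were set by a rule fixed before the data were examined. They are the 5 peaks with the highest score, the 5 widest peaks, and the 5 autosomal bins with the highest and the 5 with the lowest ratio. Regions chosen later are named as such. Coordinates are 1-based on mm9.

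Median coverage was 355 input and 374 hMeDIP fragments per autosomal 100 kb bin. The counting SD expected from the counts of each bin, as the root mean square over all tested bins, was 0.12 on the log2 scale. A peak held a median of 27 hMeDIP and 4 input fragments, so the ratio of a single peak is imprecise. The bin calls were tested on simulated counts for the same 23419 bins. These were Poisson counts, the model that the intervals assume. The simulation therefore checks the calculation and does not give the error rate of real bins. Intervals held the true value in 95.2% of all bins, nearly all of them unchanged. Among the 50 bins simulated at each fold they did so in 88.0% at 2-fold, 98.0% at 0.5-fold, 100% at 4-fold and 92.0% at 0.25-fold. Further, 100% of the 50 bins simulated at each of 2-fold, 4-fold, 0.5-fold and 0.25-fold were called in the right direction, and 0.0388% of the unchanged bins were called. The distance between reads of opposite strands was checked on chromosome 19, where hMeDIP read pairs were most frequent at 150 bp, at 1792 pairs against 1079 at 350 bp and 917 at 600 bp. The input showed 229 pairs at 150 bp and 187 at 600 bp. The deposited fragment length of 350 bp is therefore longer than the distance at which opposite strands met most often.

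The alternatives tried were scaling to the fragments outside peaks, counting each position once, leaving out 10 kb bins with extreme or no input, another overlap rule, the 46327 peaks with the highest score, merging of near peaks, other pseudocounts, other bin sizes and another threshold. Weighting by reads, centring on the median bin, leaving out fragments in peaks, a higher input minimum, 150 bp fragments and the runs of bins under other scalings were added after seeing the data. Gene annotation of peaks, profiles along genes, the gene lists and CpG density had also been planned. They were not analysed here, because they need an mm9 annotation or sequence and the gene table at hand is on GRCm38, whose coordinates were not mixed with mm9. For that reason regions are given by position and not by gene. RNA levels were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.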

Results

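Antibody-enriched and input DNA from mouse kidney were compared to locate 5hmC in the genome. The hMeDIP library held 11424027 fragments and the input library, which measures the background of the same tissue without antibody, held 8316507. No library was replicated, so every difference below is between these libraries. Its interval covers counting error only, except for the matched X difference.

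The first question was where the enriched regions lie and how strongly they stand above input. The authors' list held 92654 peaks that covered 125.4 Mb, or 4.75% of the span of chromosomes 1 to 19, X and Y as set by their highest coordinates. Peaks were short, with a median width of 1152 bp and quartiles of 874 and 1550 bp. A small set was broad: 565 peaks reached 5 kb and 27 reached 10 kb. Of all hMeDIP fragments, 28.3% (95% interval 28.3 to 28.4) lay in peaks, against 5.37% (5.35 to 5.38) of input fragments, a ratio of 5.28 (5.26 to 5.29). The median peak was 4.37-fold above input, with quartiles of 3.40 and 5.97. Under a pseudocount of 5 that median was 2.64. The interval of the ratio lay above 1 in 90644 peaks (97.8%), spanned 1 in 2010 and lay below 1 in 0. The peaks had been called on 5hmC signal, so their enrichment is not independent evidence of it.

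The peaks with the highest scores were broad blocks on different chromosomes. Across the list the score was related to width (Spearman's rho 0.62) more closely than to fold over input (0.44). A ranking by score therefore favours wide peaks. The peak with the top score of 2936.71 spanned chromosome 12, 112586139 to 112600186 (14048 bp), with 607 hMeDIP and 62 input fragments, a ratio of 7.13 (5.48 to 9.41). The second, at chromosome 15, 85903967 to 85922270, was also the widest peak of the list at 18304 bp and had a ratio of 6.49 (5.13 to 8.31). The third lay at chromosome 10, 116367178 to 116379531, with a ratio of 8.74 (6.39 to 12.2). The fourth, at chromosome 4, 154582366 to 154590417, had 430 hMeDIP and 26 input fragments and a ratio of 12.0 (8.10 to 18.6). The fifth, at chromosome 11, 98825309 to 98835776, had a ratio of 11 (7.55 to 16.6).

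Among the 5 widest peaks, the chromosome 15 and chromosome 12 regions named above took the first and the fourth place. The others were chromosome 3, 121138044 to 121153332 (15289 bp), with a ratio of 7.02 (5.35 to 9.36), chromosome 8, 119930435 to 119944736 (14302 bp), with a ratio of 6.22 (4.65 to 8.49), and chromosome 15, 58883181 to 58896584 (13404 bp), with a ratio of 6.65 (5.01 to 8.97).

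Ratios were raised next to peaks as well. In the 250 bp on either side of the midpoint of autosomal peaks the ratio was 6.61 (6.57 to 6.64), and at 9 to 10 kb from the midpoint it was 2.19 (2.19 to 2.20), in windows that include other peaks. Outside all peaks the ratio fell with distance from the nearest peak edge. It was 1.54 (1.53 to 1.55) at 500 to 1000 bp, 1.21 (1.21 to 1.21) at 2000 to 5000 bp, 1.04 (1.03 to 1.04) at 5000 to 10000 bp, 0.892 (0.890 to 0.895) at 10000 to 20000 bp, 0.726 (0.724 to 0.728) at 20000 to 50000 bp and 0.368 (0.368 to 0.369) beyond 100000 bp. The first 500 bp beside a peak broke this order, at 1.20 (1.19 to 1.20).

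**Figure D1:**
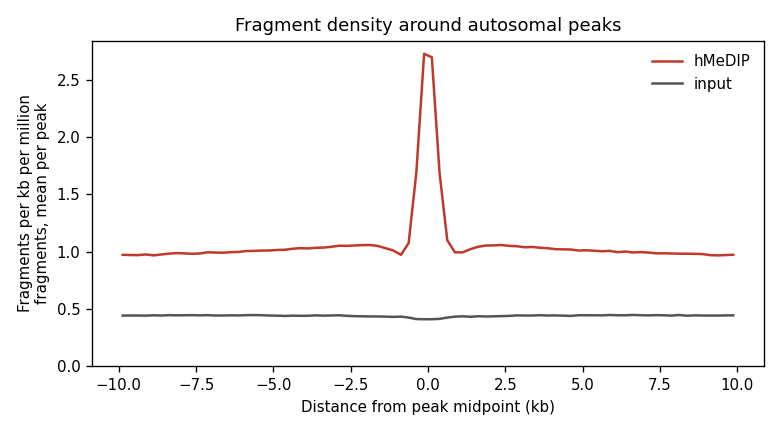
Mean fragment density around the midpoints of 92319 autosomal peaks in 250 bp steps. The x axis gives the distance from the midpoint in kb and the y axis the mean number of fragments per kb and peak, scaled by the total fragments of the library. The hMeDIP line peaks at the centre and stays above the input line to 10 kb on both sides.

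The second question was how 5hmC is spread over broad stretches of the genome. In 23419 autosomal 100 kb bins the log2 ratio had an SD of 1.08, against 0.12 expected from counting. The 95th percentile (1.32) was 10.2-fold above the 5th (-2.03). The distribution had 2 maxima. One lay at -1.8 to -1.7 with 3.53% of bins, the other at 0.3 to 0.4 with 3.25%, and the lowest class between them, at -1.1 to -1.0, held 2.41%. High bins numbered 5360 (22.9%) and low bins 11209 (47.9%). Scaling to the fragments outside peaks adds 0.40 to every log2 ratio, and the calls became 8289 high and 8826 low. Centred on the median bin, which lay at -0.42, they were 8404 high and 8724 low. High bins were therefore 32.3% of the calls under the main scaling, 48.4% when scaled outside peaks and 49.1% when centred on the median. With a threshold of 1 on the log2 scale 2392 bins were high and 8230 low, so that high bins were 22.5% of the calls.

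**Figure D2:**
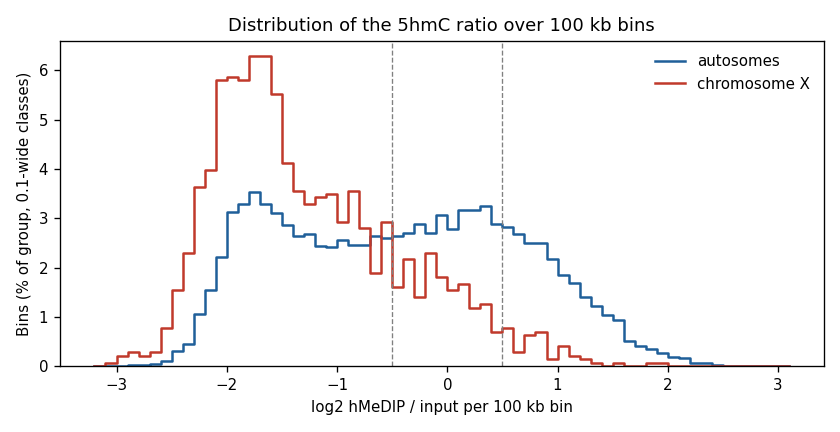
Distribution of the log2 hMeDIP over input ratio in 100 kb bins with at least 50 input fragments, as the percentage of the bins of each group in classes 0.1 wide. The dashed lines mark -0.5 and 0.5. Autosomal bins have maxima at -1.8 to -1.7 and at 0.3 to 0.4, and bins of chromosome X have theirs in the classes from -1.8 to -1.6, each with 6.28% of bins.

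The 5 bins with the highest ratios were rich in peaks, whose fragments also count in the bin ratio. The top bin, chromosome 8, 119800001 to 119900000, had 3756 hMeDIP and 342 input fragments and a log2 ratio of 3.0 (2.84 to 3.16). In it, 26 peaks covered 91.2% of the sequence, and the third widest peak of the list lay in the next 100 kb bin. Next came chromosome 15, 58800001 to 58900000, which holds the fifth widest peak, at 2.69 (2.54 to 2.85) with 23 peaks. Chromosome 8, 123000001 to 123100000, stood at 2.63 (2.46 to 2.80) with 26 peaks, chromosome 11, 120100001 to 120200000, at 2.56 (2.37 to 2.76) with 26 peaks, and chromosome 5, 143500001 to 143600000, at 2.56 (2.37 to 2.75) with 28 peaks.

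**Figure D3:**
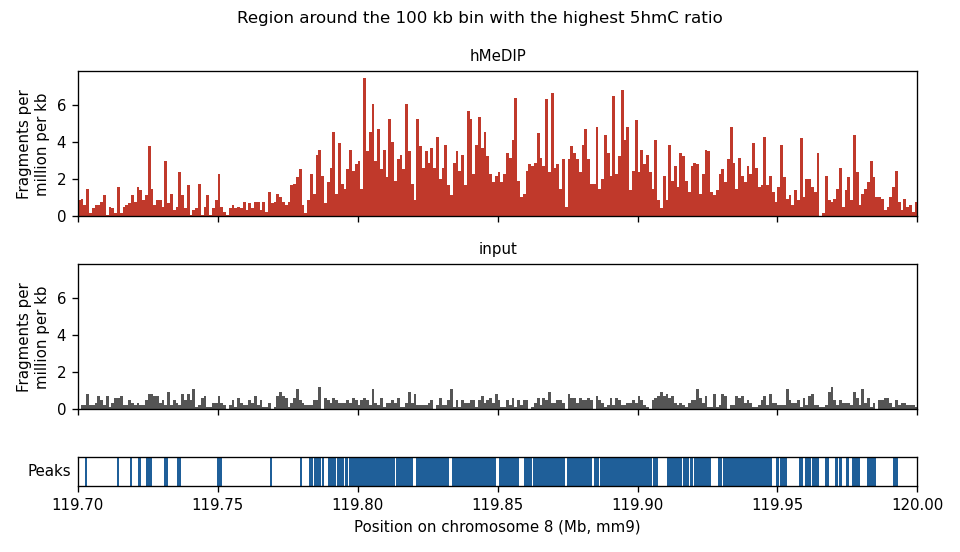
The 100 kb bin with the highest ratio and the 100 kb on either side, on chromosome 8 of mm9, with position in Mb on the x axis. The y axes give hMeDIP and input fragments in 1 kb steps, scaled by the total fragments of each library and drawn on the same scale, and the bars below mark the authors' peaks, 71 in this map of 300 kb. The hMeDIP signal is high over most of the bin, with short breaks, and extends beyond it on both sides. The input stays lower throughout the bin, and is the higher in some 1 kb steps outside it.

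The 5 lowest bins held no peak midpoint. They were chromosome 12, 115900001 to 116000000, with 10 hMeDIP and 54 input fragments and a log2 ratio of -2.89 (-4.03 to -1.90), chromosome 3, 90900001 to 91000000, and chromosome 7, 34300001 to 34400000, both with 19 and 102 fragments and -2.88 (-3.67 to -2.17), chromosome 3, 3000001 to 3100000, with 74 hMeDIP fragments and -2.86 (-3.24 to -2.50), and chromosome 14, 54100001 to 54200000, with 15 and 78 fragments and -2.84 (-3.74 to -2.03). Of these 5 bins, 4 had far fewer input fragments than the median bin (355), so their place at the bottom is imprecise. The other, chromosome 3 from 3000001, moved to -2.48 (-3.03 to -1.96) when 10 kb steps of extreme or no input were left out.

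Most runs of high or low bins were short, with medians of 3 low and 2 high bins, and a share of the bins lay in long domains. The correlation of the log2 ratio between bins was 0.87 for neighbours, 0.47 at 1 Mb and 0.10 at 5 Mb, across bins that are not independent replicates. Of the low bins, 72.7% lay in the 326 runs of 1 Mb or more (814.4 Mb in all, pooled ratio 0.367, 0.366 to 0.368). Among the fewer high bins the share was 22.2%, in 80 runs (119.1 Mb, pooled ratio 2.39, 2.38 to 2.40). Scaled to the fragments outside peaks, where high and low bins were about as many, these shares were 69.4% and 46.0%, the medians were 2 low and 3 high bins, and the longest runs were 9.9 Mb low and 9.0 Mb high. Under the main scaling the longest low domain reached 11.9 Mb on chromosome 15, 13300001 to 25200000, with a log2 ratio of -1.85 (-1.88 to -1.82). Then followed chromosome 1, 108700001 to 119500000, at -1.77 (-1.80 to -1.74) and chromosome 14, 88000001 to 98200000, at -1.84 (-1.87 to -1.81). The longest high domains were chromosome 17, 27000001 to 30800000, at 1.34 (1.32 to 1.37), chromosome 11, 115000001 to 118400000, at 1.5 (1.47 to 1.53) and chromosome 2, 165000001 to 168200000, at 1.44 (1.41 to 1.47). When the bins of each chromosome were shuffled, the longest runs in 20 shuffles were 2.4 Mb for low and 1.0 Mb for high bins, and 1.6 Mb for both when scaled outside peaks. High bins held 70713 of the 92319 autosomal peaks (76.6%), or 13.2 peaks per bin, and low bins 2012 (2.18%), or 0.18 per bin. Fragments in peaks also count in the bin ratio, so this contrast is not independent evidence.

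**Figure D4:**
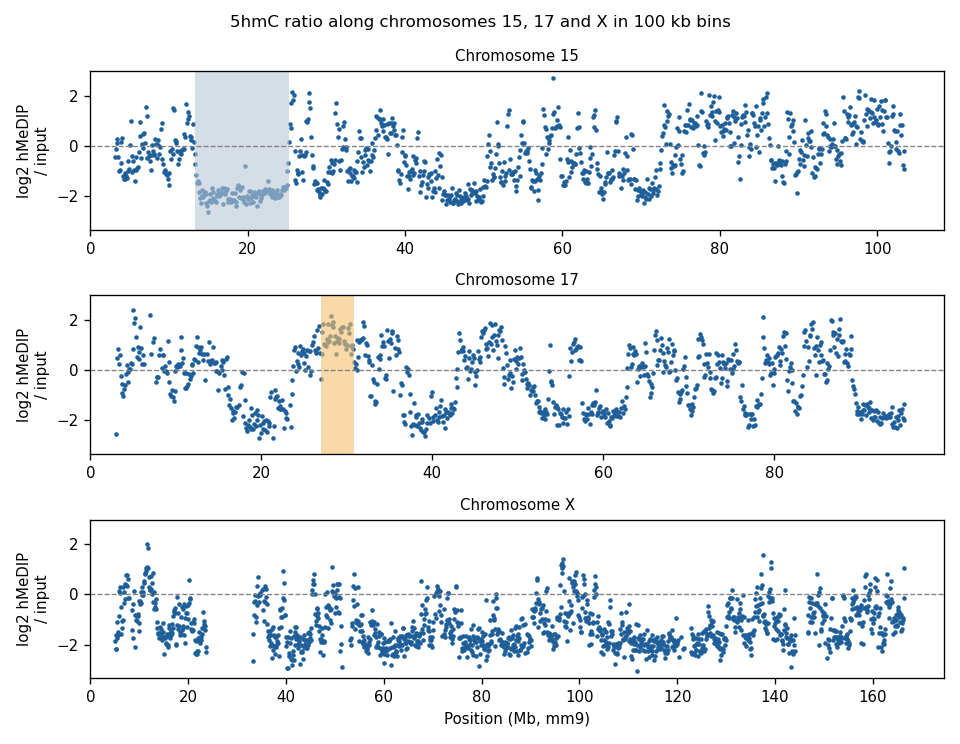
The log2 hMeDIP over input ratio in 100 kb bins along chromosomes 15, 17 and X, with position in Mb on mm9 on the x axis. Each point is 1 bin with at least 50 input fragments, the grey band marks the longest low domain (11.9 Mb) and the orange band the longest high domain (3.8 Mb). Most bins of chromosome X lie below 0.

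The third question was how chromosomes differ. The sex chromosomes and mitochondrial DNA (M) fell below every autosome. Autosomal ratios ran from 0.848 (0.845 to 0.851) on chromosome 3 to 1.24 (1.234 to 1.247) on chromosome 19, with a median of 1.03 and an SD of 0.111 over 19 chromosomes. Chromosomes 11 (1.23, 1.22 to 1.23) and 17 (1.17, 1.17 to 1.18) stood next to chromosome 19 at the upper end, and chromosomes 1 (0.885, 0.883 to 0.888) and 16 (0.899, 0.895 to 0.903) next to chromosome 3 at the lower end. Chromosome X was at 0.544 (0.540 to 0.547), chromosome Y at 0.314 (0.304 to 0.323) and mitochondrial DNA at 0.283 (0.270 to 0.296). The Y value rests on 5861 hMeDIP and 13608 input fragments, all at or below position 2902869, and the mitochondrial value on 2653 and 6830.

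**Figure D5:**
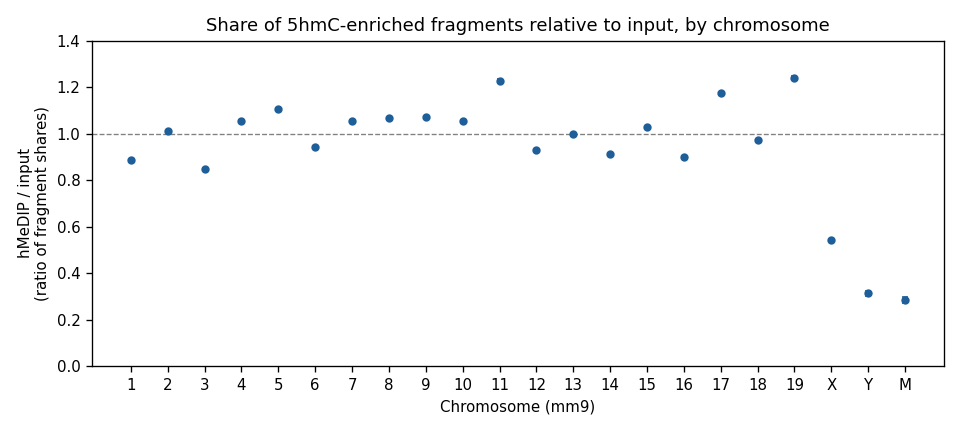
Ratio of the hMeDIP share to the input share of fragments for each chromosome, with exact 95% intervals that are mostly smaller than the points. The dashed line marks 1, the mean of the libraries. The 19 autosomes lie between 0.848 and 1.24, chromosome X lies at 0.544, Y at 0.314 and mitochondrial DNA (M) at 0.283.

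Peak density was also lower on the sex chromosomes than on any autosome. Autosomes carried 27.4 (chromosome 3) to 55.0 (chromosome 11) peaks per Mb with a median of 37.0. Chromosome X carried 335 peaks, or 2.01 per Mb, 0.0543 of the autosomal median (0.0330 among the 46327 peaks with the highest scores), and the covered part of chromosome Y carried 0. Mitochondrial DNA carried 0 peaks too, but with 16620 bp it is too short for a density. The X peaks that were called had a median fold of 5.82, against medians of 4.21 to 4.51 on the autosomes. The input density of X was 0.395 of that of the autosomes and its hMeDIP density 0.212, so fewer fragments were there to call peaks from. With fewer fragments a peak may need a higher fold to enter the list. The median folds of called peaks therefore do not compare 5hmC levels between X and autosomes. In bins, where the ratio is taken against the input of the same place, 3.56% of 1432 X bins were high and 80.8% low, against 22.9% and 47.9% on autosomes. The median X bin (-1.47) lay at the 23.0th percentile of autosomal bins. The X value minus the autosomal value was -0.30 at the 5th percentile of bins, -1.05 at the median and -0.99 at the 95th percentile on the log2 scale. Against autosomal bins matched on input density per copy, the difference of the medians was -0.37 (-0.55 to -0.08, from resampled 5 Mb blocks). The 3 highest X bins were 11600001 to 11700000 at 2.0 (1.76 to 2.24), its neighbour 11700001 to 11800000 at 1.86 (1.59 to 2.13) and 137500001 to 137600000 at 1.55 (1.20 to 1.92), chosen after the values were seen.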

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

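The tests of the X copy, the input density, the stacked loci and the amplification were chosen after the result was seen, and the others before. The test of the stacked loci replaced an undecided one, the share of repeated hMeDIP reads in the 20 fullest 10 kb bins (28.0%), after that value had been seen. The interval of the matched X difference was widened from single bins to 5 Mb blocks after it had been seen, since neighbouring bins are correlated. No biological explanation was tested, since the design names none beyond the antibody.

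In the number of reads per position, which the main comparisons did not use, 1.33% (1.33 to 1.34) of hMeDIP positions held 2 or more reads, against 0.384% (0.379 to 0.388) of input positions, which is why it is listed here. Chance meeting of reads in dense sequence is argued against as the whole source, because repeated reads outside stacked bins were 4.13 times the number expected from the local density, against 2.83 times in the input. Outside the 10 kb bins that hold a position with over 3 reads, the hMeDIP share of repeated reads was 4.37 times that of the input. That value cannot weigh a few stacked loci, because chance alone gives the libraries unlike shares there (35300 repeated reads expected in hMeDIP, 8380 in input). With the chance expectation subtracted, the hMeDIP share outside stacked bins was still higher than that of the input. It was 1.39% against 0.167% inside peaks and 0.802% against 0.191% outside. These shares argue against a few stacked loci as the whole source. Amplification of the library stays open. The share of repeated reads above chance was 1.73 times as high inside peaks as outside (0.874 in the input). That lies between the bounds set here, after the result was seen, for amplification alone and for a local source.

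The low share of hMeDIP fragments on chromosome X, at 0.212 of the autosomal density, was weighed as the second pattern. The single X of male animals is argued against as the whole cause, because it lowers the input alike and the ratio to the input was 0.544, below the lowest autosome (0.848). Coverage bias shared with the input, through base composition or mappability, cannot be told apart from a lower 5hmC level. Against autosomal bins of matched input density per copy the X median differed by -0.37 on the log2 scale (interval from resampled 5 Mb blocks -0.55 to -0.08), against -1.05 unmatched. That interval reaches both sides of the 0.3 set beforehand as the bound against this explanation, which keeps it open.

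The wide spread of the 100 kb ratios was the third pattern. Counting noise is argued against, because ratios from a random split of the fragments correlated at 0.974 across bins. Input density is argued against as the whole cause, because bins with 341 to 368 input fragments kept 0.979 of the SD of all bins, although ratio and input were related across bins (Spearman's rho 0.354, medians of -1.55 and -0.10 in the 20% of bins with the lowest and the highest input). Fragments in called peaks are argued against as the whole cause, because the ratio outside the peaks kept 0.814 of the SD. CpG density and base composition, which can shape antibody recovery, stay open and were not tested.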

How the results depend on the processing

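Weighting by reads, centring on the median bin, fragments outside peaks only, at least 200 input fragments, fragments of 150 bp and the runs of bins under other scalings were chosen after seeing the data. No direction reversed among the 18 named regions. These were chosen as extreme, with main log2 ratios of at least 2.56 in size, and scaling outside peaks shifts them by 0.40. A reversal was therefore not to be expected. The order of the median run lengths did turn, from 3 low and 2 high bins under the main scaling. It became 2 low and 3 high bins, both scaled outside peaks and centred on the median bin. Further, 2 stacked loci described further on turned when weighted by reads. For the 18 named regions, 46 of 54 values under 3 alternatives stayed within the main interval and 8 moved. Those that moved include all 5 highest bins, when scaled to the fragments outside peaks. Scaling to the fragments outside peaks raised the median peak fold to 5.77, the X, Y and mitochondrial ratios to 0.718, 0.414 and 0.373, and the share of high bins to 35.4% (8289 against 5360 bins). It multiplies every ratio by 1.32, those of the autosomes too, so X, Y and mitochondrial DNA stay below every autosome. Centring on the median bin gave 35.9% high bins (8404), and a threshold of 1 gave 10.2% (2392). The 46327 peaks with the highest scores had a median width of 1457 bp, covered 78.8 Mb and held 19.5% of hMeDIP and 3.35% of input fragments, a ratio of 5.82, with a median fold of 5.10 and an X density 0.0330 of the autosomal median. By share of length covered that density was 0.0420. Merging peaks within 1 kb gave a median width of 1241 bp. Counting any overlap of 1 bp gave shares of 29.4% and 6.60% and a ratio of 4.45. The median fold was 4.80 with a pseudocount of 0.5 and 2.64 with 5, peaks being low in input. Without 10 kb bins of extreme or no input the hMeDIP share was 28.4% and the median fold 4.36. Weighting by reads gave shares of 28.4% and 5.35%, a ratio of 5.31, a median fold of 4.32 and a mitochondrial ratio of 0.263. Fragments of 150 bp gave an hMeDIP share of 28.3%. Apart from the pseudocount and the choice of peaks, the cause was not tested. Counting each position once removed 0 fragments and so tests nothing, and is left out of these numbers. In bins of 10 kb (at least 5 input fragments) and 1 Mb (at least 500), the shares of high and low bins stayed within 1.5 times the main values. Gene annotation, gene profiles, gene lists and CpG density were not run, with their alternatives. No paired analysis was possible because each group has 1 library. Centred on the median bin, 69.2% of low and 46.4% of high bins lay in runs of 1 Mb or more. Depth limits the ratios of single peaks, with a median of 4 input fragments, and of the lowest bins, with 10 hMeDIP fragments in the lowest.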

Other observations

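The tests of peak spacing and of chromosome ends were written before their results were seen, and the test of a common floor after. Its count of bins replaced an undecided ratio (1.30) that had been seen, and the bound on that count was changed after the count was seen. The stacked loci and the distal end of X were chosen after their values were seen. The peaks of the authors' list lay close to one another. The median distance between neighbouring midpoints on autosomes was 4.95 kb, against 17.2 kb (range 17 to 17.3) in 100 random placements within sequence covered by the input. Distances above 500 kb made up 0.686% of the observed gaps and 0.031% of the random ones, and the longest gap was 7.70 Mb. Random placement is thus argued against as a description of the list. The list had 92654 peaks, and 68372 after peaks within 1 kb were merged. The spacing of merged peaks was not measured, so the distances do not describe separate 5hmC sites.

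The distal ends of chromosomes tended to be higher than the rest of the same chromosome, without passing the test. The last 5 Mb had a higher median log2 ratio than the rest on 14 of 19 autosomes, with a median difference of 0.71 and a range of -1.83 (chromosome 17) to 1.65 (chromosome 15). The exact two-sided sign test over chromosomes gave p = 0.064, and chromosomes of 1 library pair are not biological replicates. The ends of chromosomes 3, 12, 13, 17 and 18 were lower than the rest, at -1.47, -0.90, -1.38, -1.84 and -1.83. Some of the other ends lay near 0, such as chromosome 1 at 0.04 and chromosome 2 at -0.04.

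The longest low domain had a ratio of 0.278, the mitochondrial genome 0.283 (0.270 to 0.296) and chromosome Y 0.314 (0.304 to 0.323), the last beyond the counting error of the mitochondrial value. The 5 lowest bins were lower, at 0.135 to 0.140. They were picked as the lowest of 23419 bins, and 4 of them hold 10 to 19 hMeDIP fragments, so their low values do not weigh against a floor. A hypothesis is that the values of the low domain, mitochondrial DNA and chromosome Y may mark a common floor of unspecific recovery. In a one-sided Fisher's exact test with Bonferroni adjustment over 23419 bins, which compares these libraries only, 4 autosomal bins lay below the mitochondrial ratio, against at most 0.05 expected by chance, which goes against a floor at that level. Of these, 3 hold 10 kb steps of extreme input, and without such steps 1 bin lay below it. Without adjustment, 555 of the 23419 tested bins had an interval wholly below the mitochondrial ratio, among 2667 with a value below it. How many of them chance alone would give was not calculated, so this count does not weigh the hypothesis. The pooled ratio of low runs of 1 Mb or more was 1.30 times the mitochondrial ratio, above the range set for a common floor. That ratio cannot decide the question, because a bin can be called low and still lie above the mitochondrial ratio. Low bins numbered 11209, against the 2667 with a value below it. The pooled ratio of such runs can therefore exceed the mitochondrial ratio with or without a floor. The hypothesis stays undecided, since the count against it rests mostly on bins of extreme input.

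Bins of chromosome X lay more often in the lower part of the distribution. Of X bins, 66.7% were below a log2 ratio of -1, against 35.1% of autosomal bins, and within that part the medians were -1.77 and -1.64. The distal end of X was an exception. At 166400001 to 166450000, 9 peaks covered 26785 bp, with a ratio of 2.08 (1.89 to 2.30) against 1.18 (0.937 to 1.5) in the 50 kb before it. Input density there was 11.4 fragments per kb, against 1.29 over X as a whole.

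At some loci reads were stacked in both libraries. At chromosome 2, 98500001 to 98510000, there were 28381 hMeDIP and 12325 input reads, on 1547 and 1467 positions. The ratio was 1.66 by reads and 0.768 (0.714 to 0.825) by positions. At chromosome 9, 35110001 to 35120000, these ratios were 1.96 and 0.806 (0.70 to 0.929), so at these 2 loci the direction depends on whether repeated reads are collapsed. At 3 others on chromosome 9, the ratio was above 1 by reads while the interval by positions spanned 1. They were 3030001 to 3040000 with 2.13 and 0.946 (0.852 to 1.051), 3020001 to 3030000 with 2.0 and 0.998 (0.904 to 1.10), and 3000001 to 3010000 with 1.90 and 1.06 (0.949 to 1.19).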
